A study of Drosophila melanogaster with 3 samples.

How the data were processed

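The samples were 3 libraries from sqz-GFP embryos aged 0 to 16 h, sonicated to fragments of 200 to 800 bp per the labels. They form 1 group of 3 biological replicates, numbered 1, 2 and 3 by the labels. One label calls the libraries an input control, while the antibody and assay labels name a sqz ChIP-seq and the file headers show a separate control alignment; they were treated as ChIP libraries on those grounds.

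Per the file headers, the authors called peaks on dm6 in each library and in the 3 libraries together, each time against 1 control alignment shared by all; each such list holds 30000 peaks. Per the file headers, a thresholded list was then derived from these lists by the irreproducible discovery rate (IDR). This rate measures how alike peaks rank in replicates. The aligner, peak caller, their versions and the IDR threshold are not given in the sources used here. The deposited signal value of a peak is its strength as the authors' caller gave it; its scale is not stated, so it was used only to rank and describe peaks within a list. The deposited -log10 q value reached 1 ceiling per list, at which 61.4% of thresholded peaks stood, so it was not used for ranking. All 6578 thresholded peaks were the 6578 peaks of highest signal in the pooled list, so a rank in the pooled list carries the same order as the signal. The set thus matches a cutoff on the pooled signal, and a single peak in it need not be met in each library. Widths ran from 114 to 1846 bp with a median of 456 bp. Neighbouring summits lay under 500 bp apart in 680 cases, so a long region can hold several peaks. Because the lists give no read counts, depth is unknown and precision rests on the number of peaks or genes counted. The shared control means that any error in it enters all 3 lists.

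Positions are given from 1. Genes and TSSs came from Ensembl release 115 (BDGP 6.54), with 13945 protein-coding genes and 19252 distinct TSSs on chromosomes 2L, 2R, 3L, 3R, 4 and X, and sequence from the Release 6 assembly that dm6 uses. Peak ends lay within the chromosome lengths, and all 13921 gene symbols shared with the RefSeq table overlapped in position. Listed gene symbols absent from the annotation were matched through synonyms. A first automatic match had put the Delta symbol on dorsal and the nanos symbol on nitric oxide synthase; both were corrected after the first results had been seen, and no list changed its call.

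Replicate concordance was the share of thresholded summits within 100 bp of a summit among the 6578 strongest peaks of a library. Summits were classed in the order TSS-proximal (within 500 bp), 5' UTR, coding exon, 3' UTR, intron and intergenic, and compared with 1000 random placements on the same chromosome by a two-sided permutation test. Densities per chromosome were first compared with 10000 such placements over all chromosomes, a test that treats clustered peaks as independent, and then with 10000 shuffles of whole windows of 100 kb or 1 Mb among the chromosomes; only the second are reported. Each of 22 gene lists was compared with all other protein-coding genes by a two-sided Fisher's exact test on genes with a summit within 1 kb of a TSS. The lists covered the Apterous cluster, temporal factors, Notch, BMP, neuroblast and proneural genes, neuronal function, glia, muscle, gap and pair-rule, segment polarity, Hox, gut and endoderm, hemocyte, germline, trachea and epidermis, ecdysone response, neuropeptides, ribosomal proteins, proteasome, chemoreceptors, accessory gland and replication histones. Fixed words were sought on both strands within 100 bp on each side of each summit and in a paired window 1 kb to its right, or to its left where the right touched another peak, by a two-sided exact McNemar test; summits with neither window free were left out. Signal and features were related across peaks by Spearman's rho with 100000 permutations. The p-values of each family were adjusted by Benjamini-Hochberg at a threshold of 0.05. The limit for a count of 0 is 3 counts of the total.

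The tests, lists, words and rule for named genes were set before the data were examined. The rule names the gene nearest each of the 15 strongest peaks, sqz, up to 4 members per list with the strongest summit within 1 kb of a TSS (up to 2 for chemoreceptors, accessory gland and histones), and up to 3 genes in each of the 3 densest windows of 100 kb. Other genes that are named were chosen after their values were seen. Alternatives covered the peak set, overlap distance, TSS window, background, word window and controls. As a check on single replicates, the thresholded peaks met in both other libraries were used; this also asks for support in both, and the pooled list behind them still holds all 3 libraries, so no peak set made without a replicate was analysed. The added alternatives, chosen after the data were seen, were controls matched on GC content and annotation class, merging of neighbouring summits, shuffled windows and jointly moved summits, matched lists for strongly transcribed genes, and the Notch list without the E(spl) complex.

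The scripts were tested on simulated data. Of 120 feature tests on randomly placed peaks 2 had p under 0.05, and a planted TSS-proximal share of 29.1% came back as 29.3%. Of 200 random lists of 15 genes 8 had p under 0.05, and 22 of 22 planted lists with 9 hits passed. No word of 9 passed on random windows, and 200 planted words were all found. The planted lists all had the same counts and the words were searched for as written. Those outcomes were therefore fixed in advance and check the code, not the power of the tests. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.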

Results

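Squeeze (sqz) is a Krüppel-type zinc finger transcription factor of Drosophila melanogaster, known for its part in specifying neurons of the Apterous cluster in the embryonic nerve cord. Its sites on chromatin were mapped by ChIP-seq, which sequences the DNA recovered with a chosen protein, in whole embryos of mixed sex aged 0 to 16 h. The embryos came from a transgenic line expressing sqz fused to GFP. The data formed 1 group of 3 biological replicates, with no second genotype, age or treatment, so no contrast between conditions was made. Each library's list and the list of the pooled libraries held 30000 peaks, and the authors' thresholded set held 6578. The lists give no read counts, so read depth is unknown for each library, and the 95% Wilson intervals on shares cover counting error only.

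The question asked of the peak lists was where the tagged factor was found, and the strongest peak lay at the promoter of sqz itself. Its summit was at position 19164177 on chromosome 3R (dm6), inside the interval 19163697 to 19164803 and 34 bp upstream of a transcription start site (TSS) of sqz (FBgn0010768, 19164211 to 19170576, plus strand). Its signal value was 4852, 1.83 times that of the next peak, and it ranked 4, 1 and 1 among the peaks of replicates 1, 2 and 3. In all, 6 thresholded summits had the sqz TSS as their nearest, among them 1 in the 5' UTR with a signal of 1705 and 1 in an intron with a signal of 1680. Of these 6 summits, 4 were met by a summit among the strongest 6578 peaks of each of the 3 libraries. The 16 thresholded peaks within 20 kb of the gene gave 3.45 peaks per 10 kb, at the 99.7 percentile of random windows of that length. Several of these summits share an interval, as in 19163697 to 19164803 and in 19165489 to 19166619, so they need not be separate sites.

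Around sqz the unthresholded lists were also dense, with 29, 30 and 30 peaks within 20 kb in replicates 1, 2 and 3, at the 96.2, 93.8 and 94.2 percentiles of random windows. Within 10 kb they were 95.8, 96.7 and 94.4. With 50 kb on each side the library percentiles fell to 76.9, 66.0 and 71.9.

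**Figure D1:**
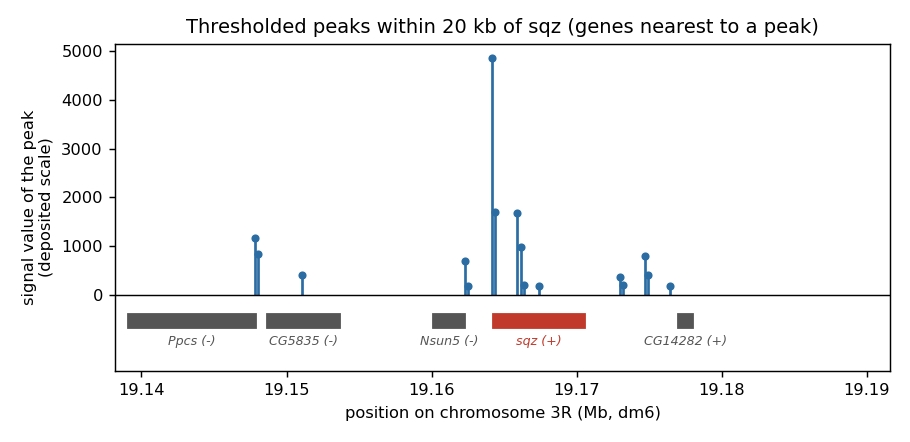
Thresholded peaks within 20 kb of sqz on chromosome 3R (dm6, position in Mb), each drawn at its summit with its deposited signal value on the vertical axis, and the genes with the nearest start site as boxes below. The peak with a signal of 4852 stands at the start of sqz, and 16 peaks lie in the window.

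Of the next 14 peaks, 8 had their summit within 500 bp of a TSS and 6 lay 1029 to 1902 bp from the nearest one. An intronic summit of CG11050 (2L, 6612716, 1029 bp from a TSS) had a signal of 2650, followed by promoter summits of Ugalt, which encodes a UDP-galactose transporter (X, 2703895, 43 bp upstream, signal 2620), and CG14100 (3L, 19590610, 86 bp upstream, signal 2543). The list went on with larp, an RNA-binding protein gene (signal 2469), cbt, a zinc finger factor gene (2387, 1368 bp from a TSS), scramb1 (2357, 1037 bp) and CG9663 (2291). Then came spen, a nuclear RNA-binding protein gene (2136, 1902 bp from a TSS), and Dad, an inhibitor of BMP signalling, with an intronic summit (3R, 17056495, 1598 bp from a TSS) at a signal of 2113. The remaining strong peaks were nearest to px (2104), Art3 (2103), the Polycomb group gene ph-p (2025), Trl, which encodes the GAGA factor (1983, 1525 bp from a TSS), and Fkbp14 (1973). Of the 15 strongest peaks, the one at CG9663 had no summit within 100 bp in the list of replicate 1, although it ranked 3 and 6 in replicates 2 and 3.

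The 100 kb window with most thresholded peaks was on 2R (18300001 to 18400000), with 33 peaks, of which 28 lay in or within 1 kb of sbb, a transcriptional regulator gene; CG14505 and GstE1 had 1 each. A window on 2R (10500001 to 10600000) held 29 peaks, 16 of them at psq and 8 at lola, both BTB-domain transcription factor genes. A window on 3R (16200001 to 16300000) also held 29, with 15 at tara, 5 at gish and 2 at bor. The median over 1342 windows was 4 peaks, and 24.8% of the windows held none.

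Most thresholded peaks were met in 2 or more libraries, and fewer in all 3. A summit among the strongest 6578 peaks lay within 100 bp of 68.2%, 80.6% and 79.2% of the thresholded summits in replicates 1, 2 and 3, a mean of 76.0% ± 6.78 (SD, n = 3), against 1.01% for random placement. In all, 5357 thresholded peaks (81.4%) were met in 2 or more libraries, 3195 (48.6%) in all 3 and 134 (2.04%) in none. Support under this cutoff followed the signal value. Of the peaks in the strongest quartile 90.2% were met in all 3 libraries, then 69.8%, 31.6% and 2.68%. The thresholded set is itself the strongest 6578 pooled peaks, so its weakest peaks lie near the cutoff used in each library. Part of the fall is thus built into the definition, and how much was not tested. With the full list of each library, 90.5%, 94.7% and 94.6% of the thresholded summits were met in replicates 1, 2 and 3. These full-list shares were not split by quartile. Spearman's rho of the rank by signal was taken across the thresholded peaks met in the full lists of both libraries. It was 0.58 between replicates 1 and 2 (5650 peaks), 0.59 between 1 and 3 (5638) and 0.73 between 2 and 3 (5923). Peaks missing from either list were left out, so rho covers only the shared ones. Peaks are regions of the same libraries and not replicates. The thresholded set derives from these libraries, so the shares are not independent of it.

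Promoters held far more summits than chance, and coding exons almost none. Summits within 500 bp of a TSS made up 37.9% of the set (36.7 to 39.0), against 11.4% ± 0.407 (SD over 1000 random placements), 3.31 times as many. Only 8 summits (0.122%) lay in coding exons outside that window, where placement gave 13.9%, and 53 (0.806%) lay in 3' UTRs, against 4.55%. Introns held 41.9% against 39.2%, intergenic sequence 18.2% against 30.1%, and 5' UTRs beyond the TSS window 1.09% against 0.796%. Of the TSS-proximal summits 60.9% were upstream of the start site, with a median position of -47 bp, and 25.9% of all summits lay over 5 kb from a TSS.

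By a two-sided permutation test the classes other than the 5' UTR had p = 0.002, the smallest that 1000 placements can give, and an adjusted p of 0.0024; the 5' UTR had an adjusted p of 0.012. All 6 classes stayed past the threshold when the summits of a chromosome were moved together, which keeps their clusters (permutation test, adjusted p from 0.0030 to 0.024). The 5' UTR call was lost with a TSS window of 1000 bp, where the ratio fell to 0.883, among peaks met in all 3 libraries (permutation test, adjusted p = 0.16), those met in replicates 1 and 3 (0.18) and against the lowest-ranked pooled peaks (Fisher's exact test, 0.086). The intron call was lost with that window (ratio 0.979), in the stronger set of 3289 peaks (0.970), and in peaks met in all 3 libraries, in replicates 1 and 3 or in 1 and 2 (ratios 1.01), and it turned to 0.791 against the lowest-ranked pooled peaks.

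**Figure D2:**
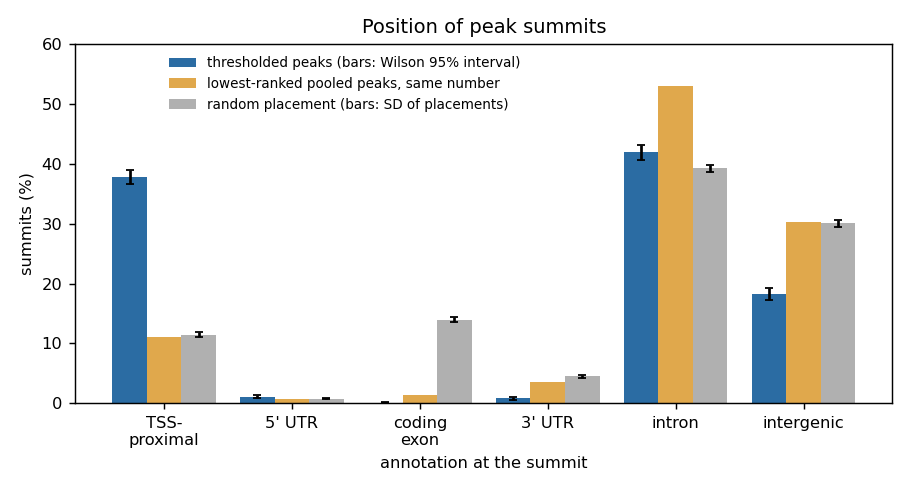
Share of summits (percent) in each annotation class for the 6578 thresholded peaks with Wilson 95% intervals, the same number of lowest-ranked pooled peaks, and random placements with the SD over 1000 placements. The TSS-proximal share was 37.9% in thresholded peaks, 11.0% in the lowest-ranked peaks and 11.4% under placement, and the coding exon share was 0.122%, 1.44% and 13.9%.

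The X chromosome carried the densest peaks and chromosome 4 the sparsest. There were 58.8 peaks per Mb on X, 1.20 times the overall 49.1, and 20.03 per Mb on chromosome 4, where 27 peaks lay (0.408 times). Chromosome 3R had 43.2 per Mb, 2R 45.2, 2L 50.4 and 3L 51.7. Peaks lie in clusters, with a variance over 100 kb windows of 5.40 times the mean, so p-values from placing each peak alone would be too small and are not given. When whole windows of 100 kb were shuffled among the chromosomes, a control chosen after the data were seen, X was past the threshold (two-sided permutation test, adjusted p = 0.014), and 3R and 4 (0.054 each), 2R (0.22), 3L (0.42) and 2L (0.65) were not. With windows of 1 Mb no chromosome was, and X had an adjusted p of 0.25 in that permutation test, so the excess on X depends on how far clusters are taken to reach. X held 21.0% of the thresholded peaks and 23.0% of the pooled peaks ranked 6579 to 30000.

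Of 13945 protein-coding genes, 2860 (20.5%) had a thresholded summit within 1 kb of a TSS. Genes of BMP signalling were among the most often marked: 11 of 14 (78.6%, 52.4 to 92.4) had a peak, against 20.5% of other genes (Fisher's exact test, adjusted p = 2.86e-05). They included the receptor gene tkv (signal 1392), Mad (709), which encodes the transducer of the pathway, and the nuclear factors shn (570) and brk (415). The BMP share was 50% (26.8 to 73.2) in the stronger set of 3289 peaks and in those met in replicates 2 and 3 or 1 and 3, and 42.9% (21.4 to 67.4) in those met in all 3 libraries. Other genes had fewer peaks as well, so the ratio went from 3.84 to between 3.31 and 3.69. The calls were kept (Fisher's exact test, adjusted p from 0.0053 to 0.019). In the Notch list 16 of 27 genes had a peak (59.3%, 40.7 to 75.5, Fisher's exact test, adjusted p = 5.25e-05), among them the protease gene kuz (1332), the ubiquitin ligase gene neur (925) and the target genes E(spl)mbeta-HLH (1087) and E(spl)m7-HLH (786). The E(spl) genes lie side by side in 1 complex and supplied 9 of the 16. Without them 7 of 16 genes had a peak (43.8%, against 28.9% in lists matched on gene length and number of TSSs). The adjusted p of Fisher's exact test was then 0.0512, so the Notch call was lost without that complex. A list of 16 also has less power than 1 of 27. Yet the smaller segment polarity list passed with 8 of 14 (57.1%, Fisher's exact test, adjusted p = 0.0070), a share near that of the full Notch list. Size alone thus does not account for the loss, and the fall of the share from 59.3% to 43.8% had a part in it. How much each contributed was not tested.

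Ribosomal protein genes formed the largest marked group, with 60 of 92 (65.2%, 55.1 to 74.2) carrying a peak, against 20.2% of other genes (Fisher's exact test, adjusted p = 3.36e-19). Their strongest summits lay a median of 18.5 bp from a TSS, as at RpS27 (signal 1128, 13 bp), RpL7 (849, 14 bp), RpL13 (815, 10 bp) and RpL11 (747, 12 bp). The proteasome genes went the other way: 3 of 48 had a peak (6.25%, 2.15 to 16.8, exact test, adjusted p = 0.021), namely Prosalpha5 (307), Prosalpha4 (192) and Rpn13 (192).

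Among lists tied to embryonic cell types, genes of trachea and epidermis were above other genes, with 9 of 13 marked (69.2%, 42.4 to 87.3, Fisher's exact test, adjusted p = 0.00074). Examples were the transcription factor genes vvl (614), salm (437) and trh (414), and crb (408), which encodes an apical polarity protein. The Apterous cluster list, the neurons in which sqz is known to act, had 9 of 17 (52.9%, 31.0 to 73.8, exact test, adjusted p = 0.0070), with sqz, dac (1084), eya (482) and cas (473). The count includes sqz, whose peak may come from extra copies carried by the transgene. This call was lost against matched lists, as given below. The temporal factors of neuroblasts had 5 of 9 (55.6%, exact test, adjusted p = 0.037), among them hb (672), cas, nub (339) and grh (258). Segment polarity genes had 8 of 14 (57.1%, exact test, adjusted p = 0.0070), with mid (610), H15 (421), nkd (370) and ci (234), and ecdysone response genes 7 of 10 (70.0%, adjusted p = 0.0032), with Eip75B (701), br (460), Hr4 (357) and ftz-f1 (356).

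Several lists showed few or no peaks. None of 26 neuropeptide genes had one (upper limit 11.5% from a count of 0, Fisher's exact test, adjusted p = 0.011), including FMRFa and Nplp1, both made by Apterous neurons. With a window of 2 kb, or with the gene body and 1 kb around it, 11.5% of them had a peak and the call was lost (Fisher's exact test, adjusted p = 0.16 and 0.14). Of 179 chemoreceptor genes 2 were marked, Or88a (509) and Gr97a (307) (1.12%, exact test, adjusted p = 3.00e-14; 6.15% with a window of 2 kb and 5.03% with gene bodies, both calls kept), and of 47 accessory gland genes 2, Sfp26Ad (225) and Acp63F (210) (4.26%, adjusted p = 0.0070). The 111 replication histone genes had 0 (upper limit 2.70%, exact test, adjusted p = 1.14e-10). They are near-identical copies in which reads may be lost or split, so this count is uncertain. Such copies are also not independent, so the limit and the p-values of this list, here and below, overstate the precision.

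The remaining 9 lists did not pass the threshold of Fisher's exact test, nor that of the test against matched lists described below. In that permutation test neuronal function genes had 20% against 45.7% in matched lists (adjusted p = 0.073). Hemocyte genes had 9.09% against 39.4% (0.10), and the others lay on both sides of their matched lists. Hox genes had 4 of 8 (lab 331, Abd-B 301, exact test, adjusted p = 0.096), glial genes 4 of 10 (loco 542, nrv2 410; 0.19), gut and endoderm 3 of 8 (cad 724, fkh 469; 0.29), muscle 5 of 18 (Tm1 615, tin 500; 0.48) and gap and pair-rule genes 4 of 15 (hb, run 428; 0.61). Neuroblast and proneural genes had 5 of 19 (brat 1052, Dr 268; 0.62), neuronal function genes 4 of 20 (elav 1117, fne 478; 1), hemocyte genes 1 of 11 (ush 358; 0.74) and germline genes 0 of 10 (upper limit 30%; 0.30).

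Genes differ in length and in their number of start sites, so the lists were also compared with lists alike in both. In a permutation test against 10000 random lists matched on gene length and number of TSSs, BMP (adjusted p = 0.0035), Notch (0.0015, and 0.44 without the E(spl) complex), trachea and epidermis (0.035) and ribosomal genes (0.0015) stayed above, and neuropeptides (0.021), chemoreceptors (0.0015) and histones (0.0035) below. The calls were lost, as the matched lists lay closer than other genes, for the Apterous cluster (52.9% against 37.7%, 0.43), temporal factors (55.6% against 43.5%, 0.85), segment polarity (57.1% against 34.3%, 0.23), ecdysone response (70.0% against 54.0%, 0.63), proteasome (6.25% against 14.8%, 0.23) and accessory gland (4.26% against 8.39%, 0.63).

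Smaller sets drawn from the thresholded peaks ended more calls: the stronger set of 3289, peaks met in all 3 libraries, and peaks met in both replicates 2 and 3, 1 and 3, or 1 and 2. The sets overlap, and peaks met in all 3 libraries came mostly from the stronger quartiles, so the lost calls are not separate tests. The number of genes with a peak fell from 2860 to between 1772 and 2114 in these sets. The Apterous cluster, at a ratio of 2.59 in the full set, had 29.4% (13.3 to 53.1) in the stronger set (ratio 2.17, Fisher's exact test, adjusted p = 0.13) and in peaks met in all 3 libraries (2.32, 0.11). It had 35.3% (17.3 to 58.7) in replicates 2 and 3 (2.33, 0.067) and 1 and 3 (2.48, 0.062). Temporal factors, at 2.71, had 33.3% (12.1 to 64.6) in the stronger set (ratio 2.46, Fisher's exact test, adjusted p = 0.18) and in all 3 libraries (2.63, 0.13). In replicates 1 and 3 they had 44.4% (18.9 to 73.3; 3.12, 0.063). Segment polarity genes, at 2.79, had 21.4% (7.57 to 47.6) in the stronger set (ratio 1.58, Fisher's exact test, adjusted p = 0.52). They had 28.6% (11.7 to 54.6) in all 3 libraries (2.25, 0.13) and in replicates 1 and 3 (2.003, 0.18), and 35.7% (16.3 to 61.2) in 2 and 3 (2.36, 0.081). Ecdysone response genes, at 3.42, had 40% (16.8 to 68.7) in the stronger set (ratio 2.95, Fisher's exact test, adjusted p = 0.079), in all 3 libraries (3.15, 0.064), and in replicates 2 and 3 (2.64, 0.081) and 1 and 2 (2.77, 0.070).

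Neuropeptide genes stayed at 0% in these sets, but other genes had fewer peaks too. The call was lost in the stronger set (Fisher's exact test, adjusted p = 0.082), all 3 libraries (0.11), and replicates 2 and 3 (0.059) and 1 and 3 (0.072). Proteasome genes, at a ratio of 0.304 in the full set, had 0.163 in all 3 libraries (Fisher's exact test, adjusted p = 0.064), 0.274 in replicates 2 and 3 (0.059) and 0.291 in 1 and 3 (0.072). Accessory gland genes, at 0.207, had 0.167 in all 3 libraries (Fisher's exact test, adjusted p = 0.064). With a window of 2 kb and with gene bodies, temporal factors stayed at 55.6% (ratios 2.20 and 2.15, Fisher's exact test, adjusted p = 0.086 and 0.088). Proteasome genes then had 14.6% (7.25 to 27.2; ratios 0.577 and 0.562, Fisher's exact test, adjusted p = 0.15 and 0.13). With gene bodies Hox (0.0012) and glial genes (0.043) passed Fisher's exact test. That window grows with gene length, and lists matched on length were not run for it. In the window of 1 kb around a TSS, both lists lay near their matched lists. Hox genes had 50% against 44.7%, and glial genes 40% against 36.1%.

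**Figure D3:**
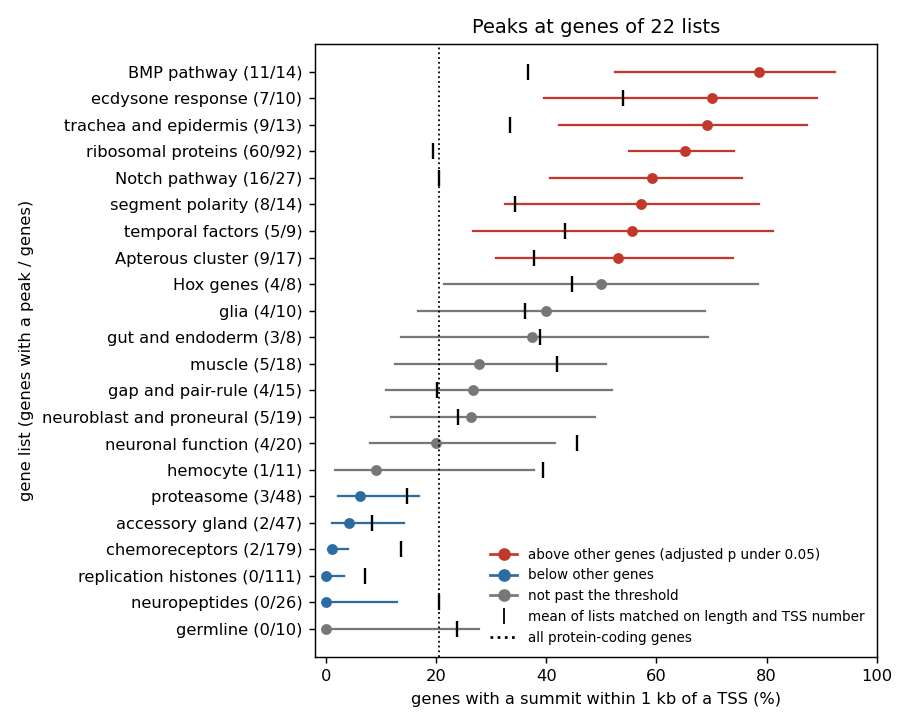
Percent of genes with a thresholded summit within 1 kb of a TSS in each of 22 gene lists, with Wilson 95% intervals; ticks give the mean of lists matched on length and TSS number and the dotted line all protein-coding genes (20.5%). BMP genes (11 of 14) and ribosomal protein genes (60 of 92) lie above both, and chemoreceptor genes (2 of 179) lie below both.

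Summits were rich in runs of A or T. A run of at least 7 A (or T on the other strand), here called an A-tract, lay within the window of 100 bp on each side of 55.8% of 6470 summits (54.6 to 57.0), against 18.4% of the paired windows 1 kb away, 3.03 times as many. Tracts were centred on the summit: 418 fell in the central 10 bp bin, against a mean of 80.6 per bin beyond 500 bp. With control windows matched on GC content instead, 24.7% of them held an A-tract and the ratio was lower, at 2.25. The ratio to the paired windows grew with the length of the run, from 1.37 for 5 bp to 4.58 for 15 bp. In the exact McNemar test 2915 pairs had the tract at the summit alone and 497 in the paired window alone, with -log10 of p at 413. The test counts each summit as independent although summits cluster. Its p-value, and those of the later McNemar and signal permutation tests, may thus be too small.

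**Figure D4:**
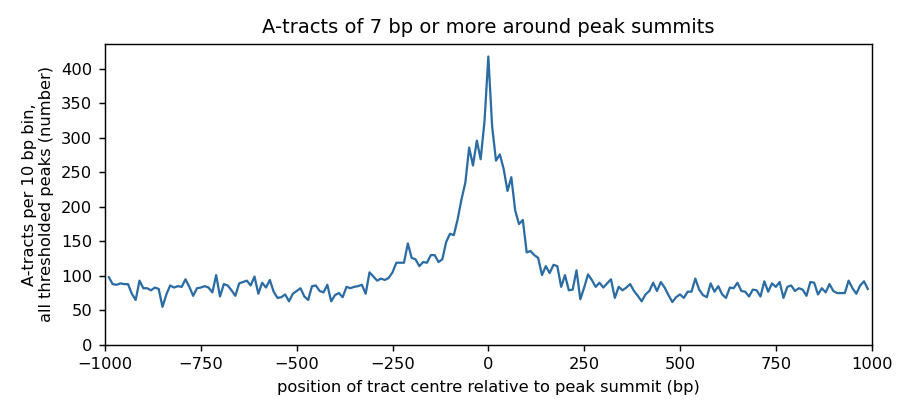
Number of A-tracts of at least 7 bp by the distance of their centre from the peak summit (bp), in 10 bp bins over all thresholded peaks. The line reaches 418 at the summit and stays near 80.6 per bin beyond 500 bp.

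Other words differed as well. The GAGA factor word GAGAGAG was at 9.12% of summits against 3.49% (exact McNemar test, adjusted p = 1.56e-39), the CA repeat CACACACA at 9.69% against 5.02% (2.45e-24), and the word TATCGATA bound by DREF and BEAF-32 at 1.95% against 0.495% (4.87e-14). The word CACCTG was less frequent at summits, 4.70% against 7.20% (3.95e-09). The words of Zelda (1.097% against 1.17%), Grainyhead (0.510% against 0.448%), Su(H) (1.19% against 1.11%) and the E-box CACGTG (2.53% against 2.30%) were not past the threshold, with adjusted p from 0.63 to 0.74. Of 2079 words of 6 bases, AAAAAA had the highest ratio (2.14), then CGCGCG (2.12) and AGAGAG (1.95), and CCAGGA the lowest (0.309). Against windows matched on GC content alone, CACGTG passed (ratio 1.33, exact McNemar test, adjusted p = 0.019), as did the Grainyhead word (ratio 3.09, 0.00065), which also passed with a window of 200 bp on each side (ratio 1.69, 0.0051). Against windows matched on GC content and annotation class, chosen after the data were seen, the DREF word (ratio 1.11, exact McNemar test, adjusted p = 0.53) and CACGTG (ratio 1.12, 0.44) were not past the threshold, and the Grainyhead word was (ratio 2.62, adjusted p = 0.0056).

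Strong peaks differed from weak ones in position and sequence, by small amounts. From the strongest to the weakest quartile the TSS-proximal share went from 49.7% to 31.0%, the share with an A-tract from 60.2% to 51.2%, that with GAGAGAG from 11.4% to 7.91% and that with the CA repeat from 11.6% to 8.33%. Spearman's rho with the signal value across the 6578 peaks was 0.15 for TSS-proximal summits and 0.070 for A-tracts (permutation test, adjusted p = 5e-05 for both, from the smallest p that 100000 permutations can give). It was 0.049 for GAGAGAG (0.0002), 0.039 for the CA repeat (0.0047) and 0.028 for TATCGATA (0.042), and the other 5 words had adjusted p from 0.10 to 0.99. The TATCGATA relation was lost when the mean rank over the 3 libraries replaced the signal value (permutation test, adjusted p = 0.32).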

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

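The controls matched on both GC content and annotation class, the merging of summits under 500 bp apart, the placements that keep clusters of peaks together, the matched lists for strongly transcribed genes and the Notch list without the E(spl) complex were chosen after the data were seen. The TSS-proximal and A-tract ratios kept their direction and their side of the threshold under each alternative run. The X density ratio was 1.22 to 1.26 in the other peak sets; with shuffled windows of 1 Mb it was 1.21 and not past the threshold. The number of peaks was 3289 for the stronger set by construction, 3195 for peaks met in all 3 libraries, and 3675 to 4359 for peaks met in both libraries of a pair, which adds a support filter and leaves the third library in the pooled list. Mean concordance moved to 83.8% with any overlap of 1 bp, 66.1% within 50 bp, 83.0% within 250 bp, 45.3% with the shorter library lists and 90.2% with the longer ones, as those definitions admit fewer or more summits. The 5' UTR ratio turned to 0.883 and the intron ratio to 0.979 with a TSS window of 1000 bp; the intron ratio was 0.970 in the stronger set and 0.791 against the lowest-ranked pooled peaks, and the cause was not tested. The number of lists above other genes was 4 in the stronger set, in peaks met in all 3 libraries and against matched lists, and 5 to 7 in peaks met in both libraries of a pair. The number below was 3 with a window of 2 kb, with gene bodies and against matched lists, 2 in peaks met in all 3 libraries, and 3 to 5 in the pairs; the cause was not tested. Of the 13 called lists, 6 kept their call in each of 9 alternatives set before the data were seen: BMP, Notch, trachea and epidermis, ribosomal proteins, chemoreceptors and histones, though Notch lost it without the E(spl) complex. The alternatives overlap, and the histone copies are not independent, so these are not separate tests. With 50 kb on each side of sqz the percentiles of replicates 1, 2 and 3 were 76.9, 66.0 and 71.9. Depth could not be varied, since the lists hold no reads.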

Other observations

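The gene families, the chromosome and rank comparisons, the matched controls for A-tracts, the comparison with the lowest-ranked peaks, the peaks at genes without A-tracts and the matched lists for strongly transcribed genes were chosen after the results were seen. Families of protein-coding genes that share a symbol stem, with at least 15 members, were tested in the same way as the gene lists, 42 in all. By Fisher's exact test 3 were above other genes and 7 below. The large and small subunit ribosomal families were above separately, RpL with 32 of 50 and RpS with 26 of 38, and so was a stem formed almost wholly of overlapping gene models at mod(mdg4), which share peaks and are not independent. Mitochondrial ribosomal protein genes had 14 of 47 for mRpL, as at mRpL41 (signal 1794), and 9 of 26 for mRpS, as at mRpS10, whose peak is the one shared with Art3. They were not past the threshold against other genes (Fisher's exact test, adjusted p = 0.26 and 0.22), but against lists matched on length and TSS number, in a permutation test, the adjusted p was 0.0028 and 0.019. The dpr family also passed only against matched lists, in the other direction. It had 1 of 21 (4.76%, against 31.3% in matched lists, permutation test, adjusted p = 0.039, and 0.22 by Fisher's exact test).

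Families of the adult senses, cuticle and detoxification had few peaks. The ionotropic receptors (Ir) had 0 of 60, the odorant receptors 1 of 59 and the gustatory receptors 1 of 60, and odorant-binding proteins 1 of 51 (Obp99b). The receptor families are parts of the chemoreceptor list above, with its same 2 marked genes, so they add no separate support. Cuticle protein genes (Cpr) had 3 of 71 (Cpr65Av, Cpr65Ay and Cpr67Fb) and cytochrome P450 genes (Cyp) 5 of 85 (Cyp310a1, Cyp317a1, Cyp4p2, Cyp6u1 and Cyp9f2). In the permutation test against matched lists the adjusted p was 0.0034 for Ir, 0.038 for odorant and 0.0098 for gustatory receptors and 0.045 for Cyp, while Obp (0.090) and Cpr (0.057) were not past the threshold. The seventh family below, genes whose symbols begin with His, had peaks at 3 members (His2Av, His3.3B and His4r, 2.61%) and was not past the threshold in the permutation test against matched lists (adjusted p = 0.093).

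Chromosome 4 and X had the most A-tracts, 1407 and 1357 per Mb, against 842 to 970 on the other arms, yet they held the fewest and the most peaks, 20.03 and 58.8 per Mb. Coding sequence, counted without the TSS class, covered 0.395% of positions at the summit, 2.72% at 200 bp to the left, 2.98% at 200 bp to the right, and 13.5% and 13.2% at 1000 bp. Among peaks ranked 6579 to 30000 the share on X was above that of the strongest 6578 in replicates 2 and 3 (23.0% against 21.0%, and 22.9% against 21.4%) but not in replicate 1 (19.1% against 19.96%). The share with an A-tract among the strongest 6578 peaks of replicate 1 was 44.9%, against 58.5% and 55.4% in replicates 2 and 3.

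The A-tracts at summits may follow from the base composition and position of the peaks, or from a bias of all called intervals. Against windows matched on GC content and annotation class, the ratio was 2.16 (exact McNemar test, p = 1.05e-257), which argues against composition and position as the whole cause. Among as many lowest-ranked pooled peaks 31.7% held an A-tract (30.6 to 32.9), against 55.6% of thresholded peaks (54.4 to 56.8), which argues against a bias equal in all called intervals; a bias that grows with signal stays open. A candidate explanation that also stays open is binding of the tagged protein itself to A-tracts, as reported for its human relative ZNF384; with no untagged or mock library analysed here, no biological explanation was tested.

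The peaks at ribosomal protein genes may reflect strong transcription at these promoters, which can make chromatin easy to recover whatever protein is tagged. Of 47 other strongly transcribed genes, fixed before the test, 27 had a peak (57.4%, 43.3 to 70.5), inside the interval of the ribosomal list and above other genes (Fisher's exact test, p = 3.00e-08; p = 0.0006 against matched lists); they included eEF2, Hsc70-4 and Act5C. Strong transcription predicts such a share, but expression was not measured in these data, so how strongly these genes were transcribed is not known here. Proteasome genes had a peak at 3 of 48 (6.25%, against 14.8% in matched lists, permutation test, adjusted p = 0.23). How active each listed proteasome gene was in these embryos is not known either. Their share thus does not decide whether activity in all cells goes with a peak. A-tracts at the promoters could add to the ribosomal excess. Of ribosomal protein genes 67.4% had one within 500 bp of a TSS (57.3 to 76.1), against 58.7% of other genes (Fisher's exact test, p = 0.11), which does not decide. As the whole cause they are argued against by the 30 ribosomal protein genes without such a tract, of which 17 had a peak (56.7%, 39.2 to 72.6), against 9.74% of other genes without one (Fisher's exact test, p = 2.70e-10); no biological explanation was tested.

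The strongest peak, at the sqz promoter, may come from extra copies of the region carried by the transgene. Within 20 kb the density of unthresholded peaks was at the 96.2, 93.8 and 94.2 percentiles of random windows in replicates 1, 2 and 3, within 10 kb at 95.8, 96.7 and 94.4, and within 50 kb at 76.9, 66.0 and 71.9; the first 2 lie on both sides of 95, so the test does not decide. The length of the transgene is not given in the sources used here, and a control from the same line would carry the same copies. Binding of the factor to its own promoter stays open and was not tested.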
